A study of Mus musculus with 33 samples.

How the data were processed

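The series holds RNA sequencing and ribosome profiling of mouse brain. Per the labels, 21 libraries came from forebrain of 20 mice in 5 groups of 4, transgenic mouse 4 being sequenced once in each of 2 batches. Another 12 libraries came from hippocampus, 6 of RNA and 6 of ribosome footprints, with 3 samples per genotype and assay. All mice were 8 weeks old. Sex was not given and was read from Xist and the Y-linked gene Ddx3y. Each sample was taken as a separate animal, apart from the repeat library. Whether hippocampus RNA and footprints of 1 number came from 1 mouse is not stated, and for knockout 1 the RNA library was female while the footprint library held Y-linked RNA. Its Ddx3y was at 44.2 CPM and its Uty at 14.1 CPM, below the other footprint libraries (67.3 to 107 and 25.5 to 33.6 CPM), so whether that library came from 1 male or from mice of both sexes is not known. Per the labels, hippocampus mice were C57BL/6NJ, but the column headers of the hippocampus RNA files and part of the protocol text name B6JN mice, so the background of these mice is less certain than that of the forebrain mice.

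Per the labels, forebrain RNA was depleted of ribosomal RNA and made into strand-marked libraries, hippocampus RNA was selected with poly(dT) and made into libraries that do not mark the strand, and footprints were prepared by a published ribosome profiling protocol. Forebrain values were deposited as estimated counts for 138835 transcripts, with effective lengths, in the layout that kallisto writes. They were not whole numbers and not normalized. Hippocampus values were deposited as counts per gene, whole and not normalized, for 54752 genes in RNA and 22523 genes in footprints, of which 21904 are annotated as protein coding. The submitters' processing notes name kallisto 0.42.4, HISAT2 2.1.0, Bowtie2 2.2.3, featureCounts (version not given) and build mm10, without saying which was used for which file. Trimming, filters on read length and the annotation release are not given in the sources used here. The TPM columns of the forebrain files were not used here, nor were sequencing reads. Positions are from the RefSeq annotation of GRCm38.

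Estimated counts were summed over the transcripts of each gene and rounded, giving 54752 genes. Total counts per library are stated in M (1000000 counts). They ran from 20.8 M to 24.2 M in B6N forebrain, 17.8 M to 23.5 M in B6N knockout, 14.7 M to 21.3 M in B6J, 17.2 M to 38.5 M in B6J transgenic (the highest being the repeat library) and 14.8 M to 20.7 M in B6J knockout. In hippocampus they ran from 41.1 M to 49.5 M for B6N RNA, 35.8 M to 60.4 M for knockout RNA, 9.1 M to 11.2 M for B6N footprints and 7.6 M to 17.9 M for knockout footprints. Values in CPM (counts per 1000000) used TMM-scaled library sizes except in the plot of stress genes per library and for single libraries, where they were unscaled. Dixon's test of single libraries used scaled values. A gene at 0 in every library of a group was given a floor of 3 counts per library, and floors cover counting error only. No pair of libraries of 1 group was as close as counting error alone would make it (the lowest chi-square over degrees of freedom was 2.92 in 46 pairs). Pairs between groups were not compared in this way.

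Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr at a minimum count of 10, robust dispersion estimates and the quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested in a comparison. A gene was called, and is said to rise or fall, at an adjusted p under 0.05. Errors of log2 fold changes are SE and errors of CPM are SD over libraries. The 16 forebrain libraries of batch 1 were fitted together, with 1 coefficient per group. The B6J knockout libraries, all in batch 2, were tested in a fit of all 21 forebrain libraries in which transgenic mouse 4 had a coefficient of its own, so that its pair of libraries alone set the batch difference. That leaves the SE of such comparisons with the error of 1 mouse's pair of libraries. Differences between effects were tested as contrasts within these fits. Hippocampus RNA and footprints were fitted apart, and translational efficiency as the interaction of assay and genotype over the 12 libraries. Common biological coefficients of variation were 7% for batch 1 forebrain, 7.9% for all forebrain, 14% for hippocampus RNA and 12.9% for footprints. There were 11 comparisons. The p-values treat libraries of a group as independent animals, and apply to these mice only.

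Altogether 39 lists of genes of stress responses, translation, synapses, mitochondria, strain differences and cell types were written before the data were examined, as were the groups, comparisons, tests and most alternatives. Lists with at least 5 measured genes were tested with camera in limma 3.58.1 at a preset correlation between genes of 0.01, which compares a list with all other genes, and adjusted over the lists of a comparison. Correlation was also estimated from the residuals of each list, and fry tested whether the genes of a list moved 1 way on balance. With the estimated correlation, the lists called were in B6N knockout minus B6N the stress response, synthetase and clock lists, in B6J minus transgenic the stress response list, in the difference of these effects and in B6J knockout minus B6J the stress response and synthetase lists, in B6J knockout minus transgenic these and the glucocorticoid list, and in the other 6 comparisons none. Counts adjusted over the list alone apply Benjamini-Hochberg to the members of that list.

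Genes were named by a rule. Per comparison it took, among called genes with a mean of at least 1 CPM whose groups did not overlap, the 10 largest rises and the 10 largest falls that have a known symbol, up to 4 called members of each called list by p, 15 genes named in every comparison, and the genes beside the n-Tr20 locus. Some genes that met the rule are not reported here. In B6N knockout minus B6N 415 genes met its first part. Xist, Ddx3y, Ttr, Prkcd, Penk, Hist1h4m, the other genes of the chromosome 17 cluster and genes called in a pair of comparisons were chosen after their values were seen. Genes whose near-identical copies share reads (histones, Entpd4, Tmem181a, Dynlt1b, and Nnt, which has a pair of gene models) have uncertain levels.

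The analysis was tested on simulated data, made from the fitted means and dispersions with 100 genes changed by 1.5-fold and 100 by 2-fold. At 1.5-fold and 2-fold the tests called 54% and 73% in B6N knockout minus B6N, 49% and 77% in B6J minus transgenic, 15% and 51% in B6J knockout minus B6J, and 20% and 50% in B6J knockout minus transgenic. In hippocampus they called 50% and 66% for RNA, 43% and 75% for footprints and 25% and 63% for translational efficiency. False calls were 3.8%, 6.7%, 5.7%, 6.7%, 14.7%, 11.9% and 3.3% of all calls in the same order. Of 200 random lists of 20 genes, camera at the preset correlation called 2 in each of the first 2 comparisons and none in the other 5, and none with an estimated correlation. Simulated genes were drawn independently, so these lists do not test what correlation between genes does to the preset p-values. Other splits of the real samples, described below, called a median of 6 (B6J knockout minus B6J) to 14 (hippocampus RNA) lists at the preset correlation.

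Replicate numbers were checked as pairs by correlating across genes, for each number, how its library in each of both groups deviated from the mean of that group. Numbers were taken as pairs by the rule that r is over 0.1 for every number. Only B6N with B6J forebrain met it, where r was 0.11 to 0.43 over the 4 numbers and 2 libraries of 4 were closest to their own number. B6J knockout with transgenic did not meet it (r of 0.02 to 0.13), though 3 libraries of 4 were closest to their own number. Whether the mice were paired is therefore not known. With the B6N and B6J numbers as a block, 501 genes and 18 lists were called between B6J and B6N, against 434 and 18 without.

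Alternatives were DESeq2 1.42.0 in place of edgeR, RLE in place of TMM scaling, no filter and a stricter filter on low counts, fits without robust estimates, an offset for average transcript length, fits of the compared groups alone, the number as a block, other handlings of the batch, limma-voom for translational efficiency, and leaving out each library in turn. A term for sex, batch 2 libraries alone, leaving out B6J knockouts 1 and 2, leaving out both libraries of hippocampus knockout 1, and the block with only B6J and B6N fitted were chosen after seeing the data. The term for sex leaves 1 male B6J knockout to set the knockout effect, and batch 2 holds 1 transgenic library. Calls of these fits are therefore not given by themselves. Other splits of the samples into groups of the same sizes were tested alike, all 35 for 4 against 4, all 10 for 3 against 3, and a random draw of 100 each for the differences of effects (raised from 50 and 40 after these were seen) and translational efficiency. Libraries that stand apart were sought with Dixon's test (critical value 0.829 for 4 samples), which could not be used on groups of 3. Pearson correlations across genes are given with a jackknife SE over libraries. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.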

Results

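The series held 33 libraries from mice aged 8 weeks that differed in n-Tr20, an arginine tRNA made in neurons that reads the AGA codon. Forebrain RNA depleted of ribosomal RNA was sequenced from 20 mice in 5 groups of 4. These were C57BL/6NJ (B6N) mice, B6N mice with n-Tr20 knocked out, C57BL/6J (B6J) mice, B6J mice with a transgene carrying the B6N form of n-Tr20, and B6J mice with n-Tr20 knocked out. The B6J strain is known to carry a variant that lowers mature n-Tr20, so B6J against B6J transgenic compared low with restored n-Tr20 within 1 strain. The 4 B6J knockout libraries were sequenced in the second batch, and transgenic mouse 4 was sequenced in both batches to bridge them. Hippocampus gave 3 poly(A) RNA libraries and 3 ribosome footprint libraries from each of B6N and B6N knockout. Footprints are the RNA fragments that ribosomes shield from nuclease. Totals ran from 14.7 M to 38.5 M (M, 1000000) estimated counts per forebrain library, 35.8 M to 60.4 M counts per hippocampus RNA library and 7.6 M to 17.9 M counts per footprint library.

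Transcripts of n-Tr20 itself were not analysed here, because these libraries count longer RNA, so the knockout label had no direct check. On GRCm38 (mm10), n-Tr20 (annotated as n-TRtct5) lies on chromosome 1 from 173390329 to 173390402, within the annotated span of Aim2 (173349547 to 173466040), next to Cadm3 (173331892 to 173368139). Neither neighbour changed in any forebrain comparison. In the B6N knockout forebrain, Aim2, a sensor of cytosolic DNA, had a log2 fold change of -0.01 ± 0.11 (SE, adjusted p = 0.992), and Cadm3, a neuronal adhesion molecule, one of 0.01 ± 0.04 (adjusted p = 0.935; n = 4 per group, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). In hippocampus RNA the same difference for Cadm3 was 0.56 ± 0.09 (adjusted p = 0.151, n = 3), with 742 ± 92.3 (SD) counts per 1000000 (CPM) in the knockout and 504 ± 14.3 in B6N. In ribosome footprints it was -0.13 ± 0.12 (adjusted p = 0.595).

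With loss of n-Tr20 on the B6N background, genes driven by ATF4 rose. ATF4 is the transcription factor of the integrated stress response, which slows translation and supplies amino acids under stress. Atf4 (ENSMUSG00000042406.8) rose 1.63-fold, from 56.7 ± 1.31 CPM in B6N to 92.4 ± 4.03 in the knockout (SD, n = 4; log2 fold change 0.71 ± 0.04 SE, adjusted p = 3.3e-13). Chac1 (ENSMUSG00000027313.3), which degrades glutathione, rose 2.82-fold, from 2.66 ± 0.508 to 7.48 ± 0.432 CPM, and Asns (ENSMUSG00000029752.12), the asparagine synthetase, rose 1.41-fold, from 63.6 ± 3.03 to 89.9 ± 3.46 CPM. Slc7a3, a transporter of cationic amino acids, rose 2.33-fold and Mthfd2, a mitochondrial folate enzyme, 1.94-fold. Stc2 rose 2.21-fold, Sesn2, a stress-induced inhibitor of mTORC1, 1.49-fold, and Atf5, another stress transcription factor, 1.6-fold. Of 40 measured members of the ATF4 and integrated stress response list, 18 rose and none fell (28 rose and 1 fell adjusted over the list alone), with a median log2 fold change of 0.27 (camera, adjusted p = 2.54e-53, and adjusted p = 5.25e-06 with an estimated correlation). All 12 measured members of the list of stress-induced tRNA synthetases, which charge tRNAs with amino acids, rose (12 adjusted over the list alone; median 0.26, adjusted p = 4.32e-35, and 9.68e-05 with an estimated correlation), among them Cars (1.4-fold), Nars (1.28-fold) and Gars (1.25-fold). Ddit3, which encodes the stress factor CHOP, did not pass (0.17 ± 0.07, adjusted p = 0.259), nor did Trib3 (1.09 ± 0.36, adjusted p = 0.135), the ribosome rescue gene Gtpbp2 (0.08 ± 0.05) or Eif2ak4 (-0.06 ± 0.05), the kinase that senses uncharged tRNA.

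**Figure D1:**
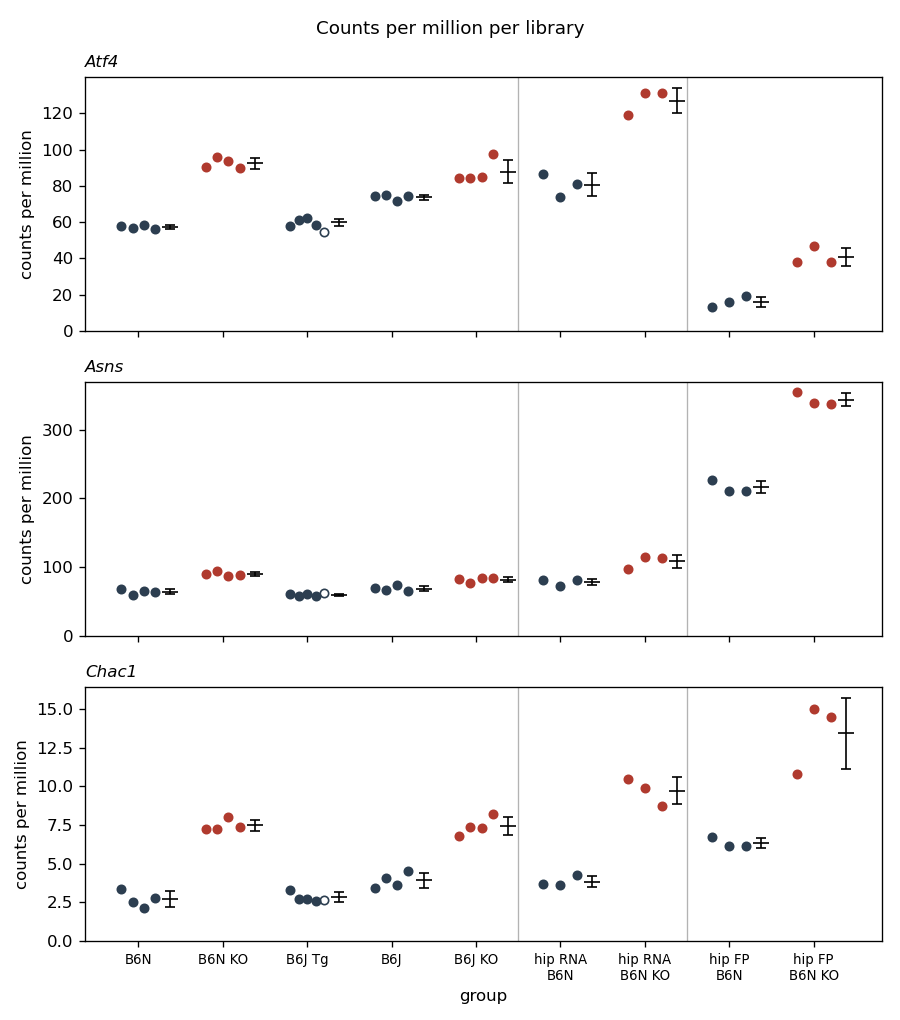
CPM (y axis, from 0) of Atf4, Asns and Chac1 in each library, by group on the x axis (KO, n-Tr20 knockout; Tg, n-Tr20 transgenic; hip, hippocampus; FP, ribosome footprints), scaled by each library's total without TMM factors. Filled points are libraries (red for knockout groups), the open circle is the second library of transgenic mouse 4, and the bar beside each group is its mean with the SD over the filled points; in forebrain and hippocampus every B6N knockout library lies above every B6N library for all 3 genes.

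Outside the stress lists, 3 of 22 neuropeptide genes rose in the B6N knockout forebrain and none fell (3 adjusted over the list alone; median 0.11, camera adjusted p = 0.00991, but 0.464 with an estimated correlation). Of these, Tac1 rose 1.18-fold. Cort, the interneuron peptide cortistatin, rose 2.41-fold, from 1.65 ± 0.362 to 3.99 ± 0.294 CPM (SD, n = 4, adjusted p = 1.9e-06), and Adcyap1, which encodes the peptide PACAP, 1.73-fold. Bdnf, a neurotrophin, rose 1.5-fold and Vgf, a secreted peptide precursor outside that list, 1.48-fold. Of 21 circadian clock genes, 4 fell and 1 rose (10 fell and 2 rose adjusted over the list alone; median -0.25, camera adjusted p = 3.58e-07, and 0.0399 with an estimated correlation). Tef, a clock output factor, fell 1.24-fold and Per3 1.29-fold, while Arntl, which drives the opposite phase, rose 1.34-fold. Of 17 interneuron markers, 3 fell and 1 rose (7 fell and 1 rose adjusted over the list alone; median -0.14, adjusted p = 7.35e-05, but adjusted p = 0.139 with an estimated correlation). Ndnf, a marker of neurogliaform cells, fell 1.29-fold and Gad1, a GABA-synthesizing enzyme, 1.14-fold, whereas Lamp5 rose 1.24-fold. Htr3a, a serotonin receptor made by some interneurons, fell 1.8-fold, from 4.76 ± 0.381 to 2.61 ± 0.579 CPM. Of 35 immediate-early genes, which neurons induce on activity, Klf4 fell 1.74-fold and Bdnf and Vgf rose (7 fell and 5 rose adjusted over the list alone; median -0.15, adjusted p = 0.0479, but 0.941 with an estimated correlation). Fos (-0.45 ± 0.19) and Arc (-0.56 ± 0.18) did not pass.

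In all, 481 of 25151 genes tested were called in the B6N knockout forebrain by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 278 rose and 203 fell, 13 by over 2-fold, and DESeq2 called 573. Among the falls were also Fmo2, 1.94-fold, Tcap, 1.94-fold, and Dynlt1b, 1.81-fold, which shares reads with near-identical copies and is uncertain. An offset for average transcript length left 174 calls, and under it the calls of Ndnf (log2 fold change -0.22, adjusted p = 0.8) and Adcyap1 (0.46, adjusted p = 0.251) ended. Leaving out 1 library gave 262 calls (without knockout 3) to 751 (without knockout 4), and the calls of Per3 (adjusted p = 0.109) and Fmo2 (adjusted p = 0.169) ended without knockout 3, that of Arntl without B6N 4 (adjusted p = 0.0587) and those of Gad1 (adjusted p = 0.0981) and Tac1 (adjusted p = 0.111) without knockout 2. Of the 8 such fits, 6 ended the call of Per3, 6 that of Tac1, 5 that of Fmo2, 4 that of Arntl, 4 that of Gad1 and 1 that of Tcap. Tissue was unequal, as Ttr, the choroid plexus gene transthyretin, was at 172, 118, 2.76 and 133 CPM in B6N 1 to 4 and at 2.59, 1.86, 253 and 1.91 in knockouts 1 to 4. Choroid plexus markers had a median of -0.27 there, with none of 17 passing (adjusted p = 0.949 with an estimated correlation).

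Some of the same stress genes were higher with low than with restored n-Tr20 within the B6J strain. Atf4 rose 1.24-fold in B6J over B6J transgenic, from 60.1 ± 2.1 to 74.8 ± 2.1 CPM (SD, n = 4; log2 fold change 0.32 ± 0.04 SE, adjusted p = 0.000137). Slc7a1, a transporter of arginine and lysine, rose 1.22-fold, Asns 1.17-fold (adjusted p = 0.0263) and Mthfd2 1.51-fold, and Cdkn1a, a cell cycle inhibitor induced by stress, 1.66-fold. Irs2, an adaptor of insulin signalling, rose 1.26-fold, and Islr2, a neuronal membrane protein, 1.32-fold. Among the falls were Flywch2, 1.55-fold, the serotonin receptor gene Htr7, 1.39-fold, and Gpr12, an orphan receptor of neurons, 1.33-fold. Chac1 did not pass (0.48 ± 0.14, adjusted p = 0.155). Of 40 measured ATF4 and integrated stress response genes, 4 rose and none fell (14 rose adjusted over the list alone; median 0.16, adjusted p = 1.28e-11, and 0.00945 with an estimated correlation). Of the 12 stress-induced tRNA synthetases, 2 rose, Cars and Yars (3 adjusted over the list alone; median 0.09, adjusted p = 1.9e-05, but 0.171 with an estimated correlation). Of 18 glucocorticoid response genes, 2 rose, Fkbp5, a chaperone of the glucocorticoid receptor, by 1.24-fold, and Cdkn1a (5 adjusted over the list alone; median 0.16, adjusted p = 4.84e-08, but 0.171 with an estimated correlation).

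Altogether 63 of 25151 genes were called between B6J and B6J transgenic (43 rose, 20 fell; DESeq2 called 162). Tissue markers also differed in median without any marker passing: thalamus markers by -0.44 and hypothalamus markers by -0.48 in B6J (adjusted p = 0.621 and 0.725 with an estimated correlation). The transcript length offset left 6 calls, Atf4 and Irs2 among them, and ended those of Asns (0.28, adjusted p = 0.189), Slc7a1 (adjusted p = 0.256) and Cars (adjusted p = 0.434). Without B6J library 3 there were 16 calls, with Asns (adjusted p = 0.158), Mthfd2 (adjusted p = 0.12) and Htr7 (adjusted p = 0.187) among those that ended, and without transgenic library 1 there were 196. Of the 8 such fits, 7 ended the call of Yars, 6 that of Htr7, 5 those of Asns and Mthfd2, and 4 those of Cars and Cdkn1a.

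The effect on Atf4 and Chac1 was larger for complete loss of n-Tr20 in B6N than for low against restored n-Tr20 in B6J. The difference of both effects was tested in 1 model, in which strain and level of n-Tr20 cannot be told apart. That difference was 0.39 ± 0.06 on the log2 scale for Atf4 (adjusted p = 0.00125) and 1.01 ± 0.19 for Chac1 (adjusted p = 0.0228), from 4 mice in each of 4 groups. Irs2 (-0.47 ± 0.07) and Islr2 (-0.47 ± 0.08) differed the other way, after rising in B6J over the transgenic group. Of 25151 genes, 15 differed between the effects (5 higher, 10 lower; 43 by DESeq2). Among 40 stress response genes 2 were higher (6 adjusted over the list alone; median 0.16, adjusted p = 6.97e-10, and 0.0217 with an estimated correlation). No tRNA synthetase passed over all genes, but 10 of 12 were higher adjusted over the list alone (median 0.18, adjusted p = 6.97e-10, and 0.0282 with an estimated correlation). Fitting without robust empirical Bayes ended the Chac1 call (adjusted p = 0.0693), and leaving out 1 library gave 3 calls (without B6N 3, or without B6N knockout 3) to 78 (without transgenic 1). Of the 16 such fits, 7 ended the call of Islr2 and 5 that of Chac1, and none that of Atf4 or Irs2.

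Strain was compared with and without restored n-Tr20. Among the genes that differed between B6J and B6N forebrain were some known to carry strain variants. Gabra2, a GABA-A receptor subunit, fell 2-fold, from 102 ± 2.27 CPM in B6N to 51.1 ± 3.77 in B6J (SD, n = 4; log2 fold change -1 ± 0.05 SE, adjusted p = 3.23e-16). Nnt, a mitochondrial transhydrogenase partly deleted in B6J, fell 1.98-fold, although a pair of annotated Nnt genes shares its reads and its level is uncertain. Ndn fell 1.73-fold. Entpd4 rose 1.9-fold and shares reads with its copy Entpd4b. The mitochondrial gene mt-Nd3 rose 5.59-fold, from 61.9 ± 14 to 346 ± 25.5 CPM. Hist1h4m had no count in any B6N library and 19.6 ± 3.93 CPM in B6J, at least 137-fold higher against a floor of 3 counts per library, and histone copies share reads. In the transgenic mice these genes also differed from B6N, with Gabra2 at -1 ± 0.05, Nnt at -1.13 ± 0.15 and mt-Nd3 at 2.44 ± 0.16.

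Atf4 rose 1.32-fold in B6J over B6N (0.4 ± 0.04, adjusted p = 9.89e-08) and Chac1 1.49-fold. Transgenic minus B6N was 0.08 ± 0.04 for Atf4 (adjusted p = 0.553) and 0.1 ± 0.14 for Chac1. The difference between these values is that of B6J minus transgenic, which passed for Atf4 and did not for Chac1. Of 40 stress response genes 5 rose and 1 fell in B6J over B6N (10 and 2 adjusted over the list alone; median 0.11, adjusted p = 3.51e-05, but 0.187 with an estimated correlation). Of 60 ion channel genes 6 rose, among them Kcnc1, a potassium channel of fast-spiking neurons, 1.17-fold (23 rose and 3 fell adjusted over the list alone; median 0.09, adjusted p = 1.07e-07, but 0.202 with an estimated correlation). Of 43 presynaptic release genes 4 rose, Pclo and Rims1 of the active zone among them, and of 49 glutamate synapse genes 4 rose, including Grin2b, an NMDA receptor subunit, 1.13-fold (adjusted p = 0.492 and 0.608 with an estimated correlation). Markers of striatum moved with these genes: 5 of 16 rose (10 adjusted over the list alone; median 0.29, adjusted p = 1.13e-13, but 0.187 with an estimated correlation), among them the dopamine receptor genes Drd2, 1.4-fold, and Drd1, 1.24-fold (adjusted p = 0.0162, but 0.0565 with the numbers as pairs). Meninges markers fell, 3 of 11 (5 adjusted over the list alone; median -0.42, adjusted p = 4.79e-09, but 0.187 with an estimated correlation), including Ogn, 1.52-fold.

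Between B6J and B6N, 434 of 25151 genes were called (305 rose, 129 fell; DESeq2 called 555), and between B6J transgenic and B6N 92 were called (68 rose, 24 fell; DESeq2 called 128). The latter included 3 ion channel genes that rose, Hcn2, Kcnc1 and Cacna1g, with a list median of 0.03, and oligodendrocyte markers had a median of 0.2 with none of 15 passing (adjusted p = 2.82e-12, but 0.317 with an estimated correlation). A fit of the B6J and B6N libraries alone called 990 genes, and 975 with their numbers as pairs, while the transcript length offset left 143, ending the call of Chac1 (0.56, adjusted p = 0.0831). Leaving out 1 library gave 216 (without B6J 4, where Chac1 had adjusted p = 0.101 and Drd2 0.0528) to 426 calls in the former, and 53 (without B6N 3) to 176 (without transgenic 1) in the latter. Without B6N 4 the call of Kcnc1 ended in both (adjusted p = 0.062 and 0.0529). Of the 8 such fits of B6J minus B6N, 5 ended the call of Chac1, 4 that of Drd1, 3 that of Drd2, 2 that of Ogn and 1 that of Grin2b, and of the 8 of transgenic minus B6N 4 ended that of Cacna1g.

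Complete loss of n-Tr20 on the B6J background was set against restored n-Tr20 and against the low level of B6J, with the batch difference taken from transgenic mouse 4. Knockouts 1 to 3 were female by Xist and all other forebrain libraries male, and choroid plexus markers were higher in the knockout, as given below. Against the transgenic group, Atf4 rose 1.72-fold (log2 fold change 0.79 ± 0.08 SE, adjusted p = 2e-06, n = 4 mice per group), Chac1 2.78-fold and Asns 1.42-fold (adjusted p = 0.00343). Stc2 rose 3.5-fold, Aldh1l2, a mitochondrial folate enzyme, 2.1-fold, and Trib3, a pseudokinase induced by ATF4, 5.74-fold from 0.34 ± 0.135 CPM (adjusted p = 0.0488). Of 40 stress response genes 11 rose and none fell (23 adjusted over the list alone; median 0.33, adjusted p = 2.8e-24, and 5.98e-05 with an estimated correlation). Of 12 stress-induced tRNA synthetases 6 rose, Cars by 1.71-fold (9 adjusted over the list alone; median 0.37, adjusted p = 1.17e-15, and 0.00258 with an estimated correlation). Among 18 glucocorticoid response genes 3 rose, Fkbp5, Map3k6 and the lipid droplet gene Plin4, the last by 3.28-fold (9 adjusted over the list alone; median 0.45, adjusted p = 1.58e-12, and 0.0346 with an estimated correlation). With a term for sex the knockout effect rests on knockout 4, the only male among the knockouts, so calls from that fit are not given. Sex is thus not separated from genotype for Stc2, Map3k6, Fkbp5 or Plin4. Cnr1, the cannabinoid receptor of neurons, fell 1.39-fold and Gpr12 1.82-fold. Of 78 ribosomal protein genes 3 rose, Rpl7a, Rpl19 and Rpl26 (24 rose and 2 fell adjusted over the list alone; median 0.17, adjusted p = 0.42 with an estimated correlation).

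Against B6J without the transgene, 27 of 25481 genes were called (23 rose, 4 fell; DESeq2 called 150), Atf4 1.39-fold (adjusted p = 0.0311) and Chgb, a granin of secretory vesicles, 1.44-fold among the rises, and Cnr1 1.37-fold among the falls. Asns (0.29 ± 0.1, adjusted p = 0.383) and Chac1 (0.99 ± 0.3, adjusted p = 0.265) did not pass. Of 40 stress response genes 1 rose (10 adjusted over the list alone; median 0.26, adjusted p = 2.47e-10, and 0.00656 with an estimated correlation). None of 12 tRNA synthetases passed over all genes and 7 rose adjusted over the list alone (median 0.25, adjusted p = 1.72e-08, and 0.0402 with an estimated correlation). Rn7sk, a noncoding RNA that restrains transcription, rose 1.66-fold with the batch term while its mean level was lower in the knockout, 17600 ± 928 against 20200 ± 743 CPM, and its log2 fold change was -0.19 without the batch term. The Atf4 call ended with the length offset (0.43, adjusted p = 0.168) and without B6J 4 (adjusted p = 0.0665), and that of Cnr1 without B6J 4 (adjusted p = 0.0825).

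Against the transgenic group, 188 of 25481 genes were called (139 rose, 49 fell; DESeq2 called 482). The knockout libraries stood apart in other ways. Xist was at 328, 354 and 344 CPM in knockouts 1 to 3 and at 2.12 in knockout 4, and below that in every other forebrain library, so the sexes were unequal. A term for sex leaves knockout 4 alone to set the knockout effect, so calls from that fit are not given and sex is not separated from genotype. Ttr was at 334 to 489 CPM in all 4 knockout libraries and at 0.768 to 411 elsewhere in forebrain. Choroid plexus markers had a median of 1.03 over the transgenic group with none of 17 passing (adjusted p = 0.638 with an estimated correlation), and interferon response genes one of 0.31 (adjusted p = 0.156 with an estimated correlation). Ribosomal RNA genes took 11.73% and 12.98% of counts in knockouts 1 and 2 and 6.58% and 6.95% in knockouts 3 and 4. With the length offset the calls of Asns (0.46, adjusted p = 0.139) and Cars (0.69, adjusted p = 0.153) against the transgenic group ended. That of Trib3 ended without knockout 4 (adjusted p = 0.0699). With a term for sex the log2 fold change of Trib3 was 2.65, set by knockout 4 alone against the transgenic group. Without knockouts 1 and 2, 108 genes were called against the transgenic group, and with no batch term 1994. Batch 2 holds only 1 transgenic library, the repeat of mouse 4, so no count is given for a fit of batch 2 alone.

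When the effects of complete loss in both strains were compared in 1 model, the difference for Atf4 was -0.08 ± 0.09 (adjusted p = 0.847), for Chac1 0.02 ± 0.28 and for Asns -0.01 ± 0.1, none passing. Of 25481 genes, 62 differed (19 higher in the B6N effect, 43 lower; DESeq2 called 285). Among 18 glucocorticoid response genes 2 were lower, Plin4 (-1.71 ± 0.32) and Tsc22d3 (-0.62 ± 0.13), and 8 adjusted over the list alone (median -0.5, adjusted p = 1.96e-14, but 0.0531 with an estimated correlation). Leaving out 1 library ended the call of Plin4 in 6 of 15 fits and that of Tsc22d3 in 7, and with the numbers as a block both ended (adjusted p = 0.0539 and 0.07). Ribosomal proteins Rpl19 (-0.47 ± 0.09) and Rpl7a (-0.51 ± 0.1) were lower and Gpr12 higher (0.9 ± 0.15). Choroid plexus markers had a median of -1.56 (adjusted p = 0.684 with an estimated correlation). With 1 library left out, the count ranged from 39 (without B6N 1) to 211 (without transgenic 1). All B6J knockouts were in batch 2 and all but knockout 4 were female, so strain, batch and sex cannot be told apart here.

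**Figure D2:**
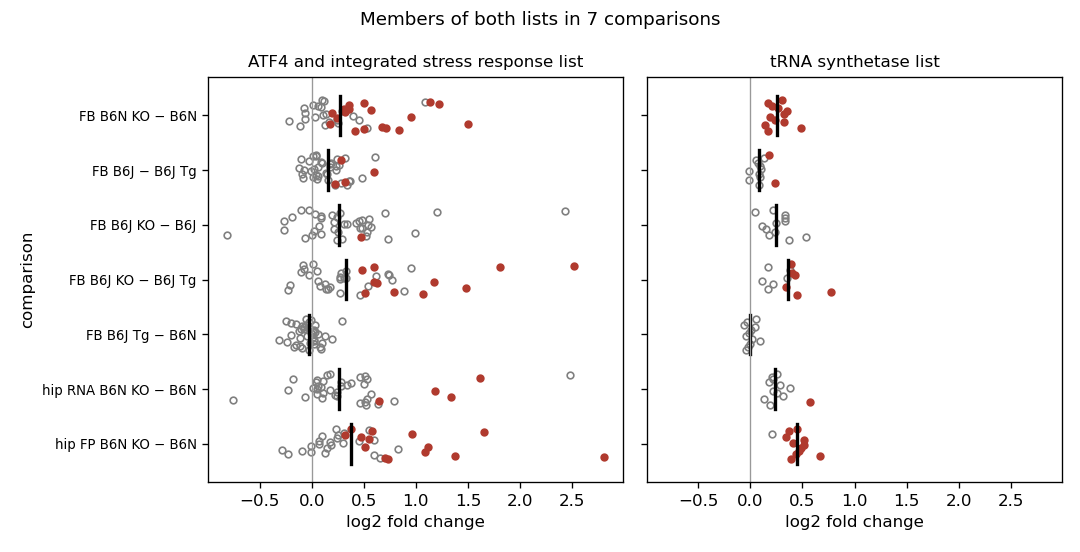
Log2 fold changes (x axis) of the members of the ATF4 and integrated stress response list and of the stress-induced tRNA synthetase list, by comparison on the y axis (FB, forebrain; hip, hippocampus; FP, ribosome footprints; KO, knockout; Tg, transgenic). Each point is a gene, filled red where its Benjamini-Hochberg adjusted p over all genes was under 0.05 and open grey otherwise, and black bars are medians; all 12 synthetases are filled in the B6N knockout forebrain and none in B6J transgenic minus B6N.

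In the hippocampus, some stress genes also rose in knockout RNA. Atf4 rose 1.57-fold, from 80.8 ± 6.47 CPM in B6N to 127 ± 5.27 in the knockout (SD, n = 3; log2 fold change 0.65 ± 0.07 SE, adjusted p = 0.0123). Slc7a3 rose 3.08-fold, Chac1 2.53-fold, Mthfd2 2.27-fold and Cars 1.48-fold, and Cort rose 2.88-fold. Ndnf fell 1.85-fold, from 43.8 ± 3.53 to 23.6 ± 1.92 CPM (adjusted p = 0.0101), and Col19a1, a collagen made by some interneurons, fell 1.81-fold. These 8 were all the genes called of 19352 (6 rose, 2 fell), while DESeq2 called 118. Asns (0.46 ± 0.07, adjusted p = 0.132) and Trib3 (2.48 ± 0.37, adjusted p = 0.0976) did not pass. Of 40 stress response genes 4 rose and none fell (20 rose and 2 fell adjusted over the list alone; median 0.26, adjusted p = 1.33e-35, but 0.0549 with an estimated correlation). Of 12 tRNA synthetases 1 rose (11 adjusted over the list alone; median 0.24, adjusted p = 5.78e-21, but 0.106 with an estimated correlation). Of 17 interneuron markers 1 fell (9 adjusted over the list alone; median -0.33, adjusted p = 5.97e-18, but 0.0549 with an estimated correlation). No oligodendrocyte marker passed over all genes and 10 of 15 fell adjusted over the list alone (median -0.39, adjusted p = 5.97e-18, but 0.299 with an estimated correlation).

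Markers of other tissue differed between these 6 RNA libraries. Prkcd, abundant in thalamus, was at 131 CPM in B6N library 2 and at 23.6 to 36.3 in the others, and thalamus markers had a median of -0.86 in the knockout (adjusted p = 0.527 with an estimated correlation). Ttr was at 2500, 1470 and 3760 CPM in B6N 1 and knockouts 1 and 3 and at 44 to 130 in the others. Leaving out 1 library gave 0 calls (without knockout 3, where Atf4 had adjusted p = 0.104 and Ndnf 0.0952) to 10, with 1 without B6N 3 and 3 without B6N 2. Testing every gene with a count gave 135 calls. Knockout 1 was female by its Xist (1230 CPM) and Ddx3y (0.331 CPM) levels.

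Ribosome footprints of some stress genes rose as well. Atf4 rose 2.61-fold in the knockout, from 15.8 ± 3.07 to 41.3 ± 4.8 CPM (SD, n = 3; log2 fold change 1.38 ± 0.16 SE, adjusted p = 0.00109), and Asns 1.62-fold, from 214 ± 8.48 to 347 ± 14.7 CPM. Slc7a1 rose 1.95-fold, Slc7a3 3.13-fold, Chac1 2.13-fold and Atf3, a stress transcription factor, 7-fold. Of 37 stress response genes measured 14 rose and none fell (18 rose and 1 fell adjusted over the list alone; median 0.38, adjusted p = 1.31e-15, but 0.23 with an estimated correlation). Of 12 tRNA synthetases 11 rose, Nars by 1.43-fold (12 adjusted over the list alone; median 0.44, adjusted p = 3.44e-15, but 0.23 with an estimated correlation). Markers of striatum rose with them, 7 of 13 measured (9 adjusted over the list alone; median 1.05, adjusted p = 1.16e-09, but 0.323 with an estimated correlation), with Drd1 3.52-fold and Tac1 2.74-fold. Penk, an opioid peptide gene abundant in striatum, was at 154, 85.6 and 163 CPM in the knockout libraries and 46.3 to 62.5 in B6N.

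Footprints of some mitochondrial, ribosomal, synaptic and histone genes fell in the knockout. Of 74 nuclear genes of oxidative phosphorylation 15 fell and 2 rose (25 fell and 2 rose adjusted over the list alone; median -0.11, adjusted p = 7.07e-06, but 0.504 with an estimated correlation); Atp5j2, a subunit of ATP synthase, fell 1.78-fold, from 218 ± 10.4 to 123 ± 8.83 CPM (adjusted p = 0.000766). Of 75 ribosomal protein genes 10 fell (20 fell and 4 rose adjusted over the list alone; median -0.13, adjusted p = 0.00198, but 0.728 with an estimated correlation), with Rps29 1.92-fold. Of 49 glutamate synapse genes 6 fell and 2 rose (14 and 4 adjusted over the list alone; median -0.04, adjusted p = 0.024, but 0.504 with an estimated correlation): Cnih2, an AMPA receptor auxiliary subunit, fell 1.84-fold and Camk2b 1.21-fold, while Gria3 rose 1.25-fold. Histone genes made up 20 of the 418 genes that fell and none of the 290 that rose, among 45 tested, and share reads between copies. Of 16 microglia markers 4 fell, the complement genes C1qa, C1qb and C1qc and Cx3cr1, and of 15 astrocyte markers 3 fell (medians -0.19 and -0.2). Of 17 interneuron markers 3 fell, Cnr1, Pvalb and Sst (5 adjusted over the list alone; median -0.25, adjusted p = 0.00124, but 0.241 with an estimated correlation).

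In total 708 of 13227 genes were called in footprints (290 rose, 418 fell; DESeq2 called 1036). The count fell to 32 without B6N library 3, 59 without knockout 2, 152 without B6N 2 and 264 without knockout 1, and the calls of Atf4, Asns, Slc7a1, Atp5j2 and Cnih2 held in all 6 such fits. Without B6N 3 the calls that ended included those of Slc7a3 (adjusted p = 0.0662), Chac1 (0.0902), Atf3 (0.13), Drd1 (0.0902), Tac1 (0.0928), Rps29 (0.11), Camk2b (0.123), C1qa (0.145), Pvalb (0.0891) and Sst (0.128). With 3 libraries per group, no split of the samples can give a share under 0.05.

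Translational efficiency, the change of footprints relative to RNA, was tested as the interaction of assay and genotype over the 12 hippocampus libraries. Atf4, whose main coding region is held back by upstream reading frames in unstressed cells, had the value 0.72 ± 0.17 (adjusted p = 0.0854, n = 3) and did not pass. Asns had 0.23 ± 0.1 (adjusted p = 0.293) and Chac1 -0.25 ± 0.23 (adjusted p = 0.64). edgeR's quasi-likelihood test called 0 of 13151 genes (smallest adjusted p = 0.0571), with 2019 at an unadjusted p under 0.05, limma-voom called 0 and DESeq2 called 439, Atf4 among them. The striatum list had a median of 0.81, with 8 of its members higher adjusted over the list alone (adjusted p = 1.56e-07, but 0.621 with an estimated correlation). Leaving out footprint library B6N 1 gave 305 calls and leaving out footprint knockout 3 gave 182.

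The effect of n-Tr20 loss in B6N forebrain was set against 3 comparisons that share no library with it. Of its 481 called genes, 407 (84.6%) had the same sign in B6J minus B6J transgenic, with a slope of 0.23 through the origin, and all 29 genes called in both had the same sign where 1.2 would be called in both if the lists were independent. Among the 29 were Atf4, Asns, Slc7a1, Mthfd2, Cars and Yars. In B6J knockout minus B6J transgenic, 335 of 481 (69.6%) had the same sign (slope 0.38), and all 34 genes called in both did (3.6 if independent). In hippocampus RNA, 407 of 468 measured (87%) had the same sign (slope 0.6), as did all 7 called in both, Atf4, Cars, Chac1, Cort, Mthfd2, Ndnf and Slc7a3 (0.2 if independent). Over all genes, which are not independent replicates, Pearson's r was -0.01 with a jackknife SE of 0.097 over libraries, 0.03 with an SE of 0.063, and 0.19 with an SE of 0.07, in that order.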

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

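The test of a smaller share of interneurons, the 3 tests on the chromosome 17 genes and the tests on other splits of the samples were chosen only after the result was seen.

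Ribosome footprints of 418 genes fell in the knockout hippocampus, with a median log2 fold change of -0.55, and these genes have shorter transcripts than the others tested (median effective length 2090 bases against 2531). The values argue against a bias with transcript length as the cause of the whole pattern. Lengths were those of transcripts, averaged over the forebrain libraries. Coding lengths were not used, so a bias with coding length stays open. After each library's trend with transcript length was removed, 94.2% of that median was left and 355 of the 418 were still called. RNA of the 401 measured there had a median of -0.07, 11.8% of the footprint change, and 302 of the 401 lay below 0. The genes were chosen by their footprint falls, which overstates the footprint change and makes the RNA share look small. The interaction of assay and genotype called 0 of 13151 genes by edgeR's quasi-likelihood test (smallest adjusted p = 0.0571) and 439 by DESeq2. Lower RNA levels as all or part of the cause therefore stay open. A single library stays open as well, since at least 91.2% of the median was left without any 1 of the 6 but the genes were chosen with all 6, and only 26 of the 418 were still called without B6N 3 and 37 without knockout 2. Also open are unequal tissue in the samples, since striatum markers moved by a median of 1.05, and a smaller share of ribosomes on these messages in the knockout, which is consistent with these values but was found and tested on the same 6 libraries. With 3 samples per group the 10 possible splits are too few for a share under 0.05, with 708 genes called in the real split and at most 0 in the others.

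Interneuron marker RNA was lower in the knockout: 15 of 17 markers lay below 0 in B6N knockout forebrain and 16 of 17 in knockout hippocampus RNA, with medians of -0.14 and -0.33, though the list did not pass with an estimated correlation (adjusted p = 0.139 and 0.0549) and oligodendrocyte markers were also lower in that hippocampus RNA (median -0.39). A smaller share of all interneurons in the tissue would lower the markers alike only if each were made by these cells alone, at an unchanged level. The markers moved apart by more than their spread in both (chi-square test of heterogeneity over n = 17 markers, p = 1.29e-13 and 3.32e-08). In forebrain, Ndnf fell 1.29-fold and Lamp5 rose 1.24-fold. A smaller share that lowers all markers alike is thus argued against, but a smaller share beside other changes of single markers stays open. Thalamus tissue in hippocampus library B6N 2 is argued against as well, since 120.5% of the hippocampus median was left without that library (-0.4), while the median of thalamus markers went from -0.86 to -0.2. Fewer cells of 1 interneuron class, or lower expression of some markers per cell, stay open and cannot be separated with tissue RNA. In B6J minus B6J transgenic 10 of 17 markers lay below 0.

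Tmem181a and its neighbour Dynlt1b on chromosome 17 (6256726 to 6308314 and 6429530 to 6440500) were lower in B6N knockout forebrain (-0.42 ± 0.04 and -0.85 ± 0.11) and lower in B6J transgenic than in B6N (-0.42 ± 0.04 and -0.72 ± 0.11). A knockout line that carries the B6J form of this region is a candidate explanation, since the larger distance of the knockout from the B6J transgenic group was 1.09 SE, within the 2 SE this needs. Reads moved between copies are argued against as the whole cause, because the sums over both families also fell, the one nearer to 0 by 6.03 SE. Tmem181a in hippocampus RNA (0 ± 0.06) differed from the forebrain value by 5.64 SE. Both regions were counted in unlike ways, however, and these genes share reads with copies. Dynlt1b was at 1.33 to 1.96 CPM in hippocampus RNA and at 8.85 to 10.7 CPM in B6N forebrain. An effect of n-Tr20 loss in every region is therefore left undecided. Of 88 other genes that differed between B6J transgenic and B6N only 5 were called in the B6N knockout, and 69 differed between that knockout and B6J transgenic. It also stays open whether the hippocampus mice carried the same form, since no genotypes were analysed here.

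Of 100 groups of 4 forebrain libraries tested, without the repeat library and with genes in TMM-scaled CPM, Dixon's test found a library that stands apart in 8, where chance gives about 1 in 20. These were the total count of B6N knockout 1 (17.8 M), Chac1 in B6N knockout 3 (8.16 CPM, others 7.29 to 7.33), Atf4 in B6N 4 (54.9 CPM, others 57.3 to 57.7) and Atf5 in B6N knockout 1 (8.53 CPM, others 7.55 to 7.68). The others were Nnt in B6N 2 (20.2 CPM, others 25 to 25.9), Gabra2 in transgenic 1 (47.9 CPM, lower than the others), Arc in transgenic 2 (270 CPM, others 167 to 175) and Aim2 in B6N 1 (4.64 CPM, higher than the others). With unscaled CPM, Chac1 in B6N knockout 3 (8.02, others 7.25 to 7.4), Atf4 in B6N 4 (56.2, others 56.7 to 58.2) and Gabra2 in transgenic 1 (47, others 51.5 to 52.9) would not stand apart by this test.

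The effects of complete n-Tr20 loss in B6N (knockout minus B6N) and of low against restored n-Tr20 in B6J (B6J minus transgenic) differed for 15 genes. This was a contrast within 1 model, in which strain and level of n-Tr20 cannot be told apart. The named ones were Chac1 (log2 difference 1.01), Atf4 (0.39), Trim66 (0.38), Dynlt1b (-0.91), Traip (-0.6), Zswim4 (-0.51), Tmem181a (-0.48), Islr2 (-0.47), Irs2 (-0.47), Mcf2l (-0.33), Mtmr4 (-0.32) and Camkk1 (-0.28). For Dynlt1b and Tmem181a a B6J form of their region in the knockout line is a candidate explanation, as given above. Leaving out 1 library ended the call of Camkk1 in 13 of 16 fits, of Zswim4 in 11, and of Traip and Trim66 in 9 each. It ended those of Mcf2l and Mtmr4 in 8 each, of Islr2 in 7, of Chac1 in 5 and of Dynlt1b in 4. The calls of Atf4, Irs2 and Tmem181a held in all 16. Among lists the median difference was 0.16 for stress response genes, 0.18 for stress-induced tRNA synthetases, 0.09 for neuropeptides, 0.09 for mitochondrial genome genes, -0.23 for clock genes and -0.27 for glucocorticoid response genes. Among marker lists it was 0.1 for oligodendrocytes, 0.09 for endothelial cells, 0.23 for meninges, -0.11 for interneurons, 0.32 for thalamus, 0.58 for hypothalamus, -0.09 for olfactory bulb and 0.05 for hippocampal pyramidal cells. Of these 14 lists, stress response genes and synthetases passed with an estimated correlation. Of 100 splits drawn from 2450, 3 gave as many genes, the real one included (2 of 50 in a first, smaller draw), and the highest other called 34, over the real 15. Of the 6 splits that keep the real B6N groups, the real one and that with 34 among them, 3 gave as many genes. The 94 splits that regroup B6N called at most 6, and they break up the effect in B6N. The share of 3 in 100 therefore does not test whether the effects differ, and chance is not excluded for the count. For lists 20 of 100 splits gave as many as the real 14, the highest 20, and with an estimated correlation 6 of 100 gave as many as the real 2, the highest other also 2, so chance is not excluded for lists.

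The effects of complete loss in both strains (B6N knockout minus B6N, and B6J knockout minus transgenic) differed for 62 genes. All B6J knockouts were in batch 2, and knockouts 1 to 3 were female, so a difference between strains is not isolated from batch and sex. Higher in the B6N effect were Gpr12 (0.9), AI593442 (0.65), Zmat3 (0.51), Ptp4a1 (0.5), Zdhhc2 (0.5), Morf4l1 (0.49), Rgs4 (0.48), Smim13 (0.46), Raph1 (0.46) and Fbxl17 (0.46). Lower were Galm (-1.9), Plin4 (-1.71), Hspb1 (-1.36), Ephx1 (-0.96), Hist2h2aa2 (-0.94), Sult1a1 (-0.86), Vipr1 (-0.78), Islr2 (-0.77), Klf15 (-0.75), Rn7sk (-0.72), Tsc22d3 (-0.62), Rpl7a (-0.51) and Rpl19 (-0.47). Without a batch term the value of Rn7sk was 0.05. Leaving out 1 library ended the call of Hspb1 in 9 of 15 fits, of Tsc22d3 in 7 and of Galm, Plin4 and Sult1a1 in 6 each. It ended that of Klf15 in 5, of Fbxl17 in 4 and of each other gene named here in at most 3. List medians were -0.16 for ribosomal proteins, -0.11 for other terminal oligopyrimidine genes, 0.29 for neuropeptides, -0.3 for interferon response, -0.28 for clock, -0.5 for glucocorticoid response, 0.37 for oligodendrocyte, -1.56 for choroid plexus, -0.74 for blood and 0.16 for striatum, and none of these 10 lists passed with an estimated correlation. Of 100 splits 3 gave as many genes, where a first draw had given 3 of 40. All 3 splits that keep the real B6N groups, the real one included, gave as many, and the 97 that regroup B6N called at most 48. The share crosses 0.05 with the size of the draw and depends on how many splits keep the B6N effect, so chance is not excluded. The highest other called 232, and it keeps the real B6N groups and so the effect in B6N, so its count is no value without effects. For lists 52 of 100 splits gave as many as the real 10, the highest 20, and with an estimated correlation another split called 4 lists where the real one called 0, so chance is not excluded for lists. The larger draws were made after the first were seen.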

How the results depend on the processing

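The term for sex, the fit of batch 2 libraries alone, the fits without B6J knockouts 1 and 2 or without both libraries of hippocampus knockout 1, and the block with only B6J and B6N fitted were chosen only after the result was seen. Of 315 called genes named per comparison, 73 were called under every alternative and without each library in turn, and of 156 called lists 11 were. RLE scaling kept 314 of the 315, the stricter filter 313 of 314, no filter 284, DESeq2 260, fits without robust estimates 252, the length offset 106 of 249 and fits of the compared groups alone 182 of 249. In B6J knockout comparisons, of 78 calls no batch term kept 50, the batch as a term with 5 transgenic libraries 76, and leaving out knockouts 1 and 2 kept 47. A term for sex leaves 1 male knockout to set the effect, and batch 2 holds 1 transgenic library, so calls kept there are not given. None of the other called genes reversed except Rn7sk without a batch term in B6J knockout minus B6J (-0.19) and in the difference of complete-loss effects (0.05), and Edf1 without it in B6J knockout minus transgenic (-0.008). Depth limits genes of low count in forebrain and hippocampus RNA: at 1.5-fold the simulated data gave 54% of changed genes called in B6N knockout minus B6N and 65.9% of those at 1 CPM or more, and 50% and 61.3% in hippocampus RNA, but 43% and 43.9% in footprints. For the values below the cause was not tested.

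Counts of called genes moved by over 1.5 times as follows. With the length offset they were 174 for B6N knockout minus B6N, 6 for B6J minus transgenic, 143 for B6J minus B6N, 55 for transgenic minus B6N, 7 for the first difference of effects (B6N knockout against B6J low n-Tr20), 12 for B6J knockout minus B6J, 67 for B6J knockout minus transgenic and 6 for the difference of complete-loss effects. With DESeq2 they were 162 for B6J minus transgenic, 43 for the first difference of effects, 150 for B6J knockout minus B6J, 482 for B6J knockout minus transgenic, 285 for the difference of complete-loss effects, 118 for hippocampus RNA and 439 for translational efficiency. No filter gave 106 for B6J minus transgenic, 46 for the first difference of effects, 135 for hippocampus RNA and 14 for translational efficiency, and fits without robust estimates gave 5 for the first difference of effects. Fits of the compared groups alone gave 990 for B6J minus B6N and 29 for B6J knockout minus transgenic. The batch as a term with 5 transgenic libraries gave 297, 1800 and 758 for B6J knockout minus B6J, minus transgenic and the difference of complete-loss effects, and no batch term gave 1983, 1994 and 159. A term for sex gave 3, 63 and 17 in that order. Against transgenic, B6J knockouts without libraries 1 and 2 gave 108 and batch 2 alone gave 742. For translational efficiency, leaving out both libraries of knockout 1 gave 2. The agreement of B6N forebrain and hippocampus RNA effects was r = 0.37 over genes of at least 10 CPM and 0.19 over all.

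With an estimated correlation in place of the preset one, the lists called were 3 for B6N knockout minus B6N, 1 for B6J minus transgenic, 0 for B6J minus B6N, 0 for transgenic minus B6N, 2 for the first difference of effects, 2 and 3 for B6J knockout minus B6J and minus transgenic, 0 for the difference of complete-loss effects, and 0 for hippocampus RNA, footprints and translational efficiency (camera, where the preset gave 13, 14, 18, 10, 14, 16, 15, 10, 19, 12 and 15). By fry they were 4, 2, 9, 3, 2, 3, 5, 1, 3, 4 and 0 in that order.

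The replicate block (numbers as pairs) gave 513, 63, 97, 15, 28, 216, 69, 6, 630 and 0 genes in the order above without B6J minus B6N. There it gave 501, and 975 with only these groups fitted. The pairing kept 287 of the 315 calls. It ended those of Drd1 and Dcn in B6J minus B6N (no other there) and, where the numbers do not pair, among others those of Htr7 and Yars in B6J minus transgenic, of Trib3 in B6J knockout minus transgenic (adjusted p = 0.0625), of Plin4 and Tsc22d3 in the difference of complete-loss effects, of Atf4 and Cars in hippocampus RNA (adjusted p = 0.0626 and 0.0843) and of Camk2b and Gria3 in footprints. Same-number correlations ranged from -0.49 to 0.43 over all pairs of groups, and in no pair of groups was every library closest to its own number. With genotype and number as 1 block, 5 genes were called for translational efficiency.

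Leaving out 1 library changed counts of genes within these ranges, naming each library that moved a count by over 1.5 times. B6N knockout minus B6N: 262 (knockout 3) to 751 (knockout 4), with 304 (B6N 1), 290 (B6N 3), 271 (knockout 1) and 288 (knockout 2). B6J minus transgenic: 16 (B6J 3) to 196 (transgenic 1), with 112, 24 and 34 (B6J 1, 2 and 4) and 36 and 29 (transgenic 3 and 4). B6J minus B6N: 216 (B6J 4) to 426, with 283, 223 and 226 (B6N 1, 3 and 4) and 285 (B6J 2). Transgenic minus B6N: 53 (B6N 3) to 176 (transgenic 1), with 56 (B6N 4). First difference of effects: 3 (B6N 3; B6N knockout 3) to 78 (transgenic 1), with 8 and 6 (B6N 1 and 4), 8 and 47 (B6N knockout 2 and 4), 34, 4, 6 and 6 (B6J 1 to 4) and 24 and 8 (transgenic 2 and 3). B6J knockout minus B6J: 10 (B6J 4) to 32, with 14 (B6J 2) and 16 (knockout 1). B6J knockout minus transgenic: 134 to 402 (transgenic 1), with 285 and 321 (transgenic 2 and 3). Difference of complete-loss effects: 39 (B6N 1) to 211 (transgenic 1), with 96 (B6N knockout 4), 112 (transgenic 3) and 134 (B6J knockout 3). Hippocampus RNA: 0 (knockout 3) to 10, with 3 and 1 (B6N 2 and 3). Footprints: 32 (B6N 3) to 916, with 152 (B6N 2), 264 and 59 (knockout 1 and 2). Translational efficiency: 0 to 305 (footprint B6N 1), with 6 (RNA knockout 1), 1 and 182 (footprint knockout 2 and 3).

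Counts of lists ranged, in the order of the lists above, over 7 (without B6N 1) to 13, 9 (without transgenic 4) to 20, 13 to 21, 8 to 12, 10 to 17, 13 to 18, 13 to 17, 9 to 13, 14 to 22, 11 to 17, and 7 (without footprint B6N 1; 9 without RNA B6N 2) to 15. Correlations of effects ranged from -0.08 to 0.03, -0.0015 to 0.05 and 0.13 to 0.22 for the 3 pairs of comparisons. Without either library of transgenic mouse 4 the batch difference could not be estimated, so these fits gave no value, and lists by codon content were not run because coding sequences were not used here.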

Other observations

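All tests on other splits of the samples were chosen only after the result was seen.

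The 6 forebrain comparisons of 4 against 4 had 35 splits each, without adjustment over comparisons. For the genes called, chance is excluded in B6N knockout minus B6N, B6J minus transgenic, B6J minus B6N and transgenic minus B6N. B6N knockout minus B6N called 481 and at most 42 in another split, B6J minus transgenic 63 and 13, B6J minus B6N 434 and 4, transgenic minus B6N 92 and 29, and B6J knockout minus B6J 27 and 3, so 1 split, the real one, gave as many in each. In B6J knockout minus B6J the real split alone parts the batches, and knockouts 1 to 3 are female. Every other split puts batch 2 knockouts in both groups, so the splits cannot decide chance there, and genotype is not isolated. For B6J minus B6N, whose numbers met the rule for pairs, the 7 other splits that part all 4 pairs called at most 2 genes and 16 lists, and the 27 that part fewer at most 4 genes and 18 lists. In B6J knockout minus transgenic 4 of 35 splits gave as many as 188, so chance is not excluded, and the highest called 542 with transgenic 1 grouped with knockouts 1, 2 and 4, which points to a structure of these samples beside genotype. For lists called with the preset correlation, chance is excluded in none of these 6: 4 of 35 splits gave as many in B6N knockout minus B6N (13, highest other 17), 12 in B6J minus transgenic (14 and 20), 2 in B6J minus B6N (18 and 18), 19 in transgenic minus B6N (10 and 20), 2 in B6J knockout minus B6J (16 and 16) and 7 in B6J knockout minus transgenic (15 and 19). With an estimated correlation the real and highest other splits called 3 and 0 lists in B6N knockout minus B6N, 2 and 0 in B6J knockout minus B6J and 3 and 1 in B6J knockout minus transgenic. Each was reached by 1 of 35 splits, the smallest share possible and not adjusted over comparisons. At that share, chance is excluded in B6N knockout minus B6N only. In both B6J knockout comparisons all knockouts were in batch 2 and knockouts 1 to 3 were female. The other splits put batch 2 knockouts in both groups, so they cannot decide chance, and genotype is not isolated. In B6J minus transgenic 3 of 35 splits gave as many as the real 1, so chance is not excluded there, nor in B6J minus B6N (0 and 0) and transgenic minus B6N (0 and 1).

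In hippocampus the 10 splits per assay are too few for a share under 0.05. RNA called 8 genes in the real split and 67 in the highest other, which groups B6N 1 with knockouts 1 and 3, the libraries with the most Ttr, and so points to a structure of the samples; 2 of 10 splits gave as many. For lists RNA gave 19 and 17 in the highest other (1 of 10 as many), and footprints 12 and 16 (7 of 10). Translational efficiency called 0 genes by edgeR (2019 at an unadjusted p under 0.05, 439 by DESeq2), which all 100 of 100 splits must reach, so the splits test nothing for that count; the highest called 153 in a split that kept the real footprint groups of B6N. It gave 15 lists against up to 21 (19 of 100), so chance is not excluded for lists.

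Further values of lists were as follows. Of 25 sterol synthesis genes none passed in B6N knockout forebrain, with a median of -0.04 (camera, adjusted p = 0.0213, but 0.751 with an estimated correlation), and of 22 chaperones of the unfolded protein response 1 rose (median 0.06, adjusted p = 0.921 with an estimated correlation). In footprints of 35 immediate-early genes 8 were higher and 1 lower adjusted over the list alone (median 0.32, adjusted p = 0.514 with an estimated correlation). In B6J knockout minus B6J the mitochondrial genome list had a median of 0.29 and a mean of -0.07, so these differ in sign.

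Because columns of hippocampus RNA are headed B6JN, it was tested, before its result was seen, whether those mice may have a B6J background. Over 46 genes that differ between B6J transgenic and B6N forebrain, the hippocampus level relative to the middle of both forebrain groups would rise with the strain difference on a B6J background and fall with it on a B6N one. Histone genes, genes of the mitochondrial genome and genes of low level in hippocampus RNA had been left out. The slope was 0.03 (two-sided permutation test, 100000 permutations, p = 0.922, with an SD of 0.29 over permutations), so the background is left undecided, and differences of region and library type keep it open.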
